A study of Mus musculus with 6 samples.

How the data were processed

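Messenger RNA of mouse kidneys was sequenced after unilateral ureteral obstruction, a surgical model in which 1 ureter is tied off and the kidney scars. The labels name 6 samples, 3 from Cd248 knockout mice and 3 from wild type mice. Groups and replicate numbers were taken from the sample titles. The table used here has a value column for 4 of them, knockout replicate 1 and wild type replicates 1, 2 and 3. Knockout replicates 2 and 3 were not analysed here. The comparison had been planned, before the data were examined, as 3 libraries against 3, and was made as 1 library against 3. No other column of per-sample values was present. The labels' protocols speak of libraries from pooled RNA, and nothing says that the replicates came from separate animals. The p-values of single genes therefore measure only the spread between these libraries, which may be technical.

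RNA was extracted with Trizol and purified on oligo(dT) beads, and libraries were sequenced, per the labels' protocols. Adapters were trimmed with cutadapt 1.9, reads were checked with FastQC and aligned with HISAT2 2.0.4, and the genome build was mm10, per the submitters' processing notes, which list these names without their roles. The program that made the expression values and its gene annotation are not given in the sources used here. The deposited table gives each of 33679 genes an FPKM value (fragments scaled to transcript length and to the library's mapped fragments) in each library, rounded to 2 decimals, per the file headers. The authors' fold change in the deposited table is a ratio, the FPKM of the knockout library divided by the mean FPKM of the 3 wild type libraries. It matched that quotient for 100% of genes with at least 1 FPKM in both the knockout library and the wild type mean. The match allowed for rounding by a margin above 0.01 that grew with the fold change. The deposited log2 fold change is the log2 of that ratio, with values of 0 replaced by a small number. The deposited p-value and q-value columns are the authors' own, rounded, from a test that is not given in the sources used here. Genes the authors marked as significant had an absolute log2 fold change of at least 1 and a q-value of at most 0.05.

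Read depth is unknown. The table holds no counts, and low FPKM values multiplied by transcript length showed no steps of whole reads, so no counting intervals were computed. FPKM summed to 304425.6 in the knockout library and to 267394.4, 279294.1 and 285321.5 in wild type replicates 1, 2 and 3. An FPKM of 0 can be a failed estimate, so such genes are described as listed at 0 and given no fold change.

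Values were analysed as log2(FPKM + 1), a scale that understates the change of low genes. Genes with a mean of at least 0.5 FPKM over the 4 libraries were tested, which left 16871 genes. Each gene was fitted with limma's moderated linear model with a mean-variance trend, two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The fit had 2 residual degrees of freedom and 2.32 prior degrees of freedom. With 1 knockout library, the spread comes from the wild type libraries alone, and the knockout library is assumed to vary like them. On simulated data of this layout with 16871 genes, the same fit called 96 of 250 genes changed by 1 on the log2 scale, 215 of 250 changed by 2, 242 of 250 changed by 4, 242 of 250 changed by 5 and 51 of 83355 unchanged genes. A simulated list of 34 genes lowered by 1 was called in 5 of 5 runs, and unchanged lists were called in 5 of 200 tests at an unadjusted p under 0.05. Genes were simulated independently of each other, and changed genes and all lists were drawn from the higher expressed genes. These rates therefore do not tell how often the list test errs where the genes of a list move together.

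Gene lists for pathways, cell types and RNA quality, 37 in number, were fixed before the data were examined, and 35 had at least 5 tested members. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and beside it with camera at an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction. As a description of these libraries, each list median was set against 10000 random lists of the same size, drawn within 50 bins of mean expression. Annotation terms in the table with 10 to 500 tested genes were tested with camera in the same way. At the preset correlation, camera compares the genes of a list with the other genes as if they were nearly independent. Its p-values then rest mainly on scatter among genes, not on spread between libraries. No camera test of a wild type library set apart is given here. The genes named in the text were chosen by a rule fixed before the data were examined: Cd248, 12 genes of fibrosis and kidney injury, the 10 largest called differences in each direction with at least 1 FPKM in the higher group and the knockout library outside the wild type range, predicted genes excepted, and up to 4 members of each list with the smallest unadjusted p. Other genes are said to have been chosen after their values were seen. Immunoglobulin genes are those with an immunoglobulin biotype in the table, 239 in number. Coordinates are those of GENCODE release M21 on the same mouse assembly, matched by gene identifier for 99.68% of genes, and are 1-based.

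Alternatives planned before the data were examined were a pseudocount of 0.1 FPKM, no filter on low values, a mean of at least 2 FPKM, scaling to the same FPKM total, median centring, quantile normalization, library weights, a fit without the trend, and fits without each wild type library. Added after the data were seen were a test without the immunoglobulin genes and a rescaling on the genes outside the immunoglobulin loci and the mitochondrial genome. Each wild type library was also set against the remaining pair of wild type libraries, a comparison added after the data were seen. Leaving out the knockout library leaves no comparison. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.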

Results

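Gene expression was measured by mRNA sequencing in obstructed kidneys of mice lacking Cd248 and of wild type mice. Cd248 encodes endosialin, a transmembrane glycoprotein of fibroblasts and pericytes. Values were available here for 1 knockout library and 3 wild type libraries, so each knockout value is a single measurement and the error given is that of the wild type libraries. Across genes, the log2 values of the wild type libraries correlated pairwise with Pearson's r of 0.975, 0.975 and 0.978, and those of the knockout library correlated with them at 0.932, 0.932 and 0.940. Genes are not independent replicates, and these coefficients describe the libraries only. Read depth is unknown. Between 14535 and 14820 genes reached at least 1 FPKM in a library.

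Cd248 (ENSMUSG00000056481; mm10, chromosome 19, 5068078 to 5070682, plus strand) was listed at 0 FPKM in the knockout library, and at 9.03, 9.57 and 8.78 FPKM in wild type replicates 1, 2 and 3. The difference was -3.34 on the log2(FPKM + 1) scale (SE 0.10; limma adjusted p = 0.0030), and -6.53 with a pseudocount of 0.1 FPKM. It was the only gene listed at 0 in 1 library with at least 5 FPKM in the other 3. An exact permutation test of its 4 values gave p = 0.25, the smallest p that 1 library against 3 allows. The direction followed the labels. The 14 tested neighbours of Cd248 on chromosome 19 had a median difference of 0.01, whose sign changed with the scaling (-0.10 with the same FPKM total), and 0 of 14 passed limma's test (camera adjusted p = 0.531).

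The comparison asked which genes differ in the obstructed kidney when Cd248 is absent; the series title names mechanotransduction in scar-forming fibroblasts. The knockout library held lower levels of matrix and contractile genes and far higher levels of immunoglobulin genes. Acta2, the smooth muscle actin of myofibroblasts, was 3.49 times lower, Fn1 (fibronectin) 2.60 times and Col1a1 (type I collagen) 2.37 times lower than the wild type mean. Igkc, the constant region of the kappa light chain, was 46.1 times higher. In all, 122 of 16871 genes passed limma's test at an adjusted p under 0.05, 108 higher and 14 lower in the knockout library. Immunoglobulin genes made up 98 of the 108. When wild type replicate 1, 2 or 3 was set against the remaining pair of wild type libraries, 0, 19 and 0 genes passed limma's test, and 53, 73 and 45 passed when the knockout library was set against the same pairs. At an unadjusted p under 0.05 these counts were 1300, 470 and 766 for the wild type libraries and 1695, 1117 and 1882 for the knockout library. Most genes that passed the adjusted threshold for the knockout library against a pair were immunoglobulin genes. Its other passing genes were fewer, against every pair, than all the genes that passed for wild type replicate 2. With the immunoglobulin genes left out of the test, 2 genes passed, Cd248 and Mzb1 (adjusted p = 0.0219 for each), and the adjusted p of the other 13 lower genes lay between 0.0779 and 0.196. In the 3 fits of the knockout library against a pair, 2, 1 and 4 genes were lower, and of the 14 lower genes Cd248 alone stayed past the threshold.

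Among the lower genes, those of the matrix and of the contractile apparatus stood beside regulators of other kinds. Acta2 (chromosome 19, 34241090 to 34255590) was at 38.9 FPKM in the knockout library against 136 ± 7.81 FPKM (SD, n = 3), a difference of -1.78 (SE 0.11, adjusted p = 0.0153). Col1a1 (chromosome 11, 94936224 to 94953042) was at 68.8 against 163 ± 6.21 FPKM, a difference of -1.23 (SE 0.10, adjusted p = 0.0313). Fn1 (chromosome 1, 71585520 to 71653200) was at 41.0 against 107 ± 9.05 FPKM, a difference of -1.35 (SE 0.13, adjusted p = 0.0456). Col12a1, a fibril-associated collagen, was at 17.2 against 53.1 ± 3.68 FPKM (-1.57, adjusted p = 0.0192), and Tpm2, a tropomyosin, at 9.01 against 23.4 ± 1.53 FPKM (-1.29, adjusted p = 0.0295). Rxfp1, a relaxin receptor, was at 0.28 against 3.75 ± 0.58 FPKM (-1.89, adjusted p = 0.0350; -3.33 with a pseudocount of 0.1 FPKM). Inhba, a subunit of activin A, was at 1.43 against 7.31 ± 0.82 FPKM (-1.77, adjusted p = 0.0291). Dtx3l, a ubiquitin ligase, was at 2.93 against 9.79 ± 0.16 FPKM (-1.46, adjusted p = 0.0132). Nnt, the mitochondrial transhydrogenase, is listed under 2 overlapping gene models that could share reads, so its values are uncertain. The first (ENSMUSG00000025453) was at 3.32 against 10.3 ± 0.77 FPKM (-1.39, adjusted p = 0.0298), and the second (ENSMUSG00000116207) was at 4.42 FPKM in the knockout library and listed at 0 in the wild type libraries. Apart from Cd248, none of the 14 lower genes passed without wild type replicate 1, without replicate 2 or without replicate 3.

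Of the fibrosis and injury genes fixed in advance that did not pass, several lay below all wild type libraries. Ccn2, a connective tissue growth factor, was at 50.4 FPKM against 168 ± 22.3 FPKM (SD, n = 3; -1.71, adjusted p = 0.0554), and Lcn2, the injury marker lipocalin 2, at 84.4 against 173 ± 4.98 FPKM (-1.02, adjusted p = 0.0514). Col1a2 was at 50.1 against 107 ± 10.1 FPKM (adjusted p = 0.105), Col3a1 at 83.2 against 191 ± 41.5 FPKM (adjusted p = 0.287), Postn at 4.55 against 10.9 ± 2.57 FPKM (adjusted p = 0.342) and Vim at 44.7 against 75.6 ± 9.35 FPKM (adjusted p = 0.287). Tgfb1 was at 13.3 against 16.0 ± 0.98 FPKM (adjusted p = 0.493) and Yap1 at 11.7 against 13.2 ± 0.72 FPKM (adjusted p = 0.610). Havcr1, the proximal tubule injury marker KIM-1, was at 261 FPKM against 160 ± 65.2 FPKM (adjusted p = 0.665), and its wild type values ranged from 85.6 to 206 FPKM. Ccn2, Lcn2 and Col1a2 passed under 3, 5 and 1 of 13 alternatives. They did not pass with the immunoglobulin genes left out, nor in any fit without 1 wild type library.

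**Figure D1:**
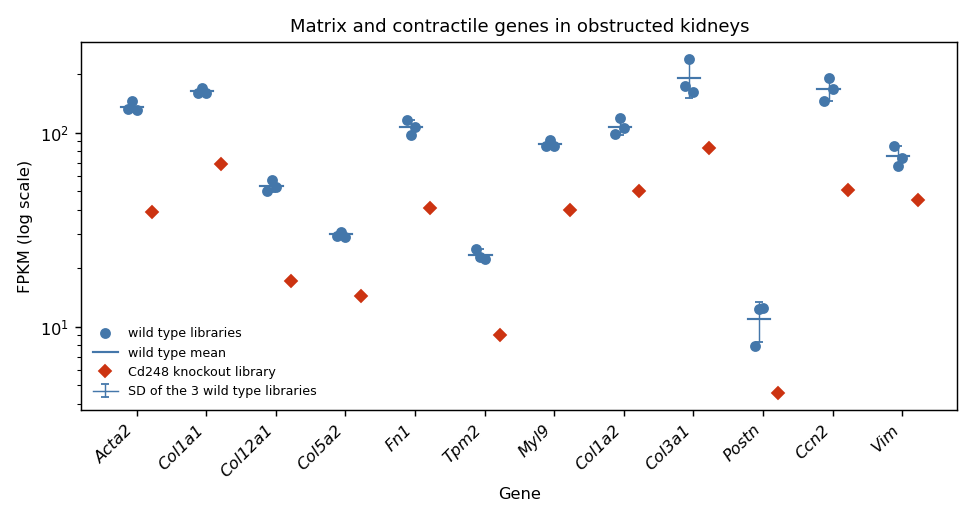
FPKM on a log axis for 12 matrix and contractile genes; circles are the 3 wild type libraries with their mean and SD, and diamonds the single knockout library. The knockout value lies below all wild type values for each gene shown, as for Acta2 at 38.9 FPKM against a wild type mean of 136 FPKM.

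Lists of matrix and mesenchymal genes were lower. Of 34 interstitial matrix genes, 4 were lower by the test over all genes (Col1a1, Fn1, Col12a1 and Col5a2), 0 were higher and 30 did not pass; adjusted over the list alone, 25 were lower. Their median difference was -0.90, with 32 below every wild type library, where chance gives 25% per gene (camera adjusted p = 9.60e-23, adjusted p = 0.607 with an estimated correlation, fry adjusted p = 0.291). That 25%, here and below, assumes a knockout library no further from the wild type libraries than they are from each other. Over the tested genes its log2 differences from them had an SD of 0.53 to 0.56, against 0.32 to 0.34 between wild type libraries. Each wild type library set against the other wild type libraries gave a median for this list between -0.22 and 0.26. Collagen processing genes had a median of -0.41 (0 of 22 passed, 6 adjusted over the list alone, camera adjusted p = 4.06e-10), with Fkbp10, a collagen chaperone, at 10.7 against 19.5 ± 1.36 FPKM. Matrix proteases and their inhibitors had a median of -0.49 (0 of 25, 5 over the list alone, camera adjusted p = 3.90e-06), and basement membrane genes one of -0.30 (0 of 22, 1 over the list alone, camera adjusted p = 1.56e-05). Single wild type libraries reached -0.26 for the basement membrane list, and its median was -0.18 without wild type replicate 2. Among fibroblast and myofibroblast markers the median was -0.58 (1 of 24 passed, Acta2, 14 over the list alone, camera adjusted p = 8.77e-11), with Tagln, an actin-binding protein of contractile cells, at 55.9 against 127 ± 12.9 FPKM. Pericyte and smooth muscle markers had a median of -0.51 (0 of 15, 2 over the list alone, camera adjusted p = 5.32e-07), with Cnn1 (calponin 1) at 1.49 against 5.40 ± 0.69 FPKM. The CD248 lectin family and its binding partners had a median of -0.40, and the 2 of 10 members past the test, Fn1 and Col1a1, also belong to the matrix list (3 over the list alone, camera adjusted p = 4.39e-06). Each of these 7 calls was lost with an estimated correlation (adjusted p = 0.607 for each) and with fry (adjusted p between 0.291 and 0.414). Urothelium markers (median -1.86, camera adjusted p = 7.21e-05), endothelial markers (-0.43, 6.21e-09) and immediate early and heat shock genes (-0.39, 5.32e-07) were lower in the same library (adjusted p = 0.607 for each with an estimated correlation).

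Lists of adhesion and signalling genes fell as well, with medians of -0.17 to -0.36. In the same library the medians of pericyte (-0.51), endothelial (-0.43) and urothelium (-1.86) markers and of the immediate early and heat shock genes (-0.39) lay lower still. Of 40 genes of adhesion and actomyosin mechanotransduction, 2 were lower, Tpm2 and Myl9, the regulatory light chain of myosin (39.9 against 87.0 ± 3.61 FPKM, adjusted p = 0.0346), and 10 were lower adjusted over the list alone. The median was -0.27, against -0.14 to 0.09 for single wild type libraries (camera adjusted p = 1.72e-10). YAP and TAZ target genes, which respond to mechanical tension, had a median of -0.36 (0 of 21, 6 over the list alone, camera adjusted p = 1.09e-06), and the YAP and TAZ regulators one of -0.17 (0 of 17, 0 over the list alone, camera adjusted p = 0.0017), which became -0.29 with the same FPKM total. TGF-beta and BMP signalling genes had a median of -0.25, and Inhba was the only 1 of 37 to pass (3 lower and 2 higher over the list alone, camera adjusted p = 4.35e-06), and the median was -0.38 with the same FPKM total. Id2, a BMP-responsive inhibitor of transcription, was at 82.4 against 50.2 ± 3.57 FPKM (adjusted p = 0.186). WNT signalling genes had a median of -0.25 (0 of 31, 1 over the list alone, camera adjusted p = 5.94e-05), with Sfrp1, a secreted WNT antagonist, at 20.5 against 34.6 ± 0.67 FPKM (adjusted p = 0.0677). Without wild type replicate 2 the median of the WNT list was -0.15, inside the range of -0.16 to 0.23 of single wild type libraries, and with a pseudocount of 0.1 FPKM it was -0.39. With an estimated correlation, the adjusted p of each of these 5 lists was 0.607.

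Immunoglobulin and plasma cell genes rose in the knockout library. Of 176 tested immunoglobulin genes, 98 were called higher and 174 had a positive difference. The filter used the mean over all 4 libraries, so genes near 0 in wild type were tested only if high in the knockout library. The positive sign of such genes was fixed by the filter. All immunoglobulin genes, tested or not, made up 5.99% of the FPKM total in the knockout library and 0.202%, 0.164% and 0.113% in wild type replicates 1, 2 and 3. Many variable and joining segments are similar in sequence and may share reads, so single segment values are uncertain. The 10 largest called differences were all of immunoglobulin genes, from Ighv9-3 (174 against 1.72 ± 0.39 FPKM, 6.02 on the log2 scale, adjusted p = 0.0030) to Ighv1-52 (203 against 0.77 ± 0.65 FPKM, 6.91, adjusted p = 0.0135), with Ighg2c, the constant region of an IgG heavy chain, at 765 against 10.3 ± 5.57 FPKM (6.19, adjusted p = 0.0313). Ighv1-52 lost its call without wild type replicate 2 (0.0627) or 3 (0.0889), and Ighg2c without replicate 1 (0.214) or 2 (0.121), while Ighv9-3 and Mzb1 passed under all alternatives run. Of 15 B and plasma cell markers, 10 were higher and 13 were higher adjusted over the list alone, with a median of 3.04 (camera adjusted p = 2.71e-21, adjusted p = 0.417 with an estimated correlation, fry adjusted p = 0.0499), of 1.88 with no filter and of 1.0 with the immunoglobulin genes left out. Mzb1, a chaperone of antibody-secreting cells, was at 17.6 against 1.26 ± 0.08 FPKM (3.04, SE 0.10, adjusted p = 0.0034). Chosen after their values were seen, Igkc (chromosome 6, 70726435 to 70726966) was at 4153 against 90.1 ± 28.9 FPKM (adjusted p = 0.0190), Igha, the IgA heavy chain constant region, at 1042 against 24.6 ± 10.7 FPKM (adjusted p = 0.0457), and Jchain, which links IgA and IgM multimers, at 310 against 7.54 ± 2.83 FPKM (adjusted p = 0.0195). Igkc and Igha lost their calls without any 1 wild type library (adjusted p between 0.0738 and 0.106 and between 0.0792 and 0.196), and Jchain without replicate 2 or 3 (0.0987 and 0.119). Ighd, the IgD constant region of naive B cells, was at 1.35 against 1.35 ± 0.51 FPKM (adjusted p = 0.985), and its sign changed with the scaling. The 10 higher genes outside the immunoglobulin loci were Mzb1 and Ly6c2, named by the rule, and Jchain, Pou2af1, Derl3, Cd79a, Tent5c, Slpi, Gm49909 and the second Nnt model, named after their values were seen. Gm49909 and the second Nnt model were listed at 0 in all wild type libraries and were tested only because of their knockout values. Their calls rest on the spread that limma borrows from other genes.

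**Figure D2:**
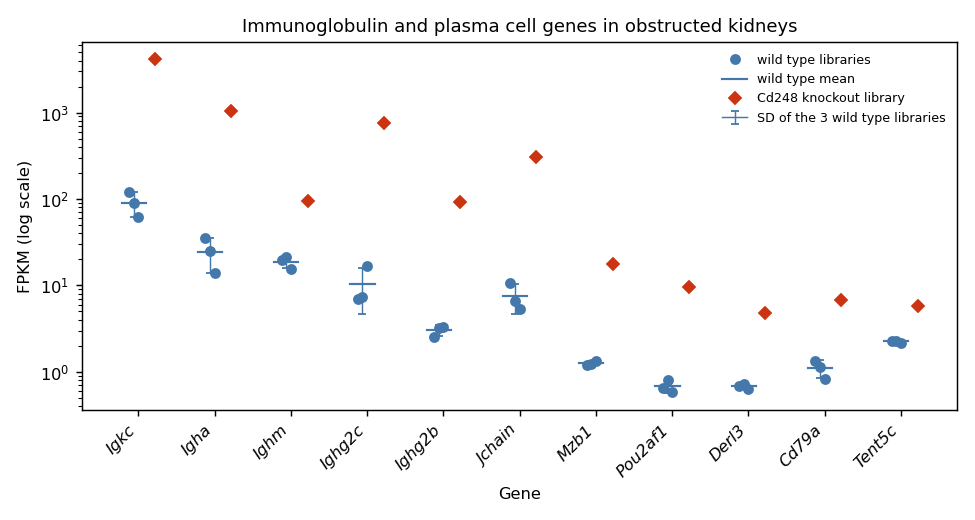
FPKM on a log axis for 11 immunoglobulin and plasma cell genes; circles are the 3 wild type libraries with their mean and SD, and diamonds the single knockout library. The knockout value lies above all wild type values for each gene shown, as for Igkc at 4153 FPKM against a wild type mean of 90.1 FPKM.

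Other immune lists moved less. T and NK cell markers rose with a median of 0.38 (0 of 21 passed, 0 over the list alone, camera adjusted p = 7.93e-08), with Gzma, a protease of cytotoxic granules, at 2.68 against 1.17 ± 0.24 FPKM. Dendritic cell and MHC class II genes had a median of 0.32 (0 of 16, 0 over the list alone, camera adjusted p = 3.29e-04). It became 0.20 with the same FPKM total and 0.15 with quantile normalization, both inside the range of -0.23 to 0.22 of single wild type libraries. Interferon response genes were mixed, with 21 of 37 below every wild type library and 11 above every one. Their median was -0.23 (0 of 37 passed, 8 lower and 1 higher over the list alone, camera adjusted p = 0.0025). Complement and coagulation genes fell by a median of 0.25 (0 of 28, 0 over the list alone, camera adjusted p = 0.0214, and 0.0610 with libraries scaled to the same FPKM total, between 0.0097 and 0.607 over its alternatives). With an estimated correlation the adjusted p of these 4 lists was 0.607. Macrophage and monocyte markers had a median of -0.02, opposite in sign to camera's direction (adjusted p = 0.969), and Ly6c2, a surface marker of inflammatory monocytes, was the 1 of 29 that rose (7.44 against 2.48 ± 0.11 FPKM, adjusted p = 0.0275; between 0.144 and 0.155 without 1 wild type library). The list median was 0.06 without wild type replicate 1 and -0.13 without replicate 2 (camera adjusted p = 0.0224, between 0.0224 and 0.992 over its alternatives). Neutrophil markers had a median of -0.57 (0 of 9, camera adjusted p = 0.0506), which became -0.34 without wild type replicate 1 and -0.96 without replicate 2 (3.17e-06), and stayed at -0.57 with the immunoglobulin genes left out (0.0449, between 3.17e-06 and 0.824 over its alternatives). Chemokines and cytokines had a median of -0.18 (0 of 36, camera adjusted p = 0.416), which became -0.27 without wild type replicate 2 (0.0222) and -0.04 without replicate 1 (0.999). The unfolded protein response had a median of -0.01, with a mean, a camera direction and a median without wild type replicate 1 or 2 of the opposite sign (0 of 25, camera adjusted p = 0.760).

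Metabolic lists were higher in the knockout library by camera. Fatty acid oxidation and peroxisome genes rose with a median of 0.34 (0 of 34 passed, 0 over the list alone, 28 above every wild type library where chance gives 25%, camera adjusted p = 9.62e-07), and of 0.21 without wild type replicate 1 or with the same FPKM total. Oxidative phosphorylation genes had a median of 0.20 (0 of 47, 0 over the list alone, camera adjusted p = 5.38e-09), and single wild type libraries spanned -0.177 to 0.140 for this list. Scaling to the same FPKM total moved the median of all genes by -0.11 and that of this list to 0.07, and quantile normalization moved the list to 0.12. Both list medians lay inside that span, as did the lowest median without 1 wild type library, 0.136. Proximal tubule markers had a median of 0.55 (0 of 34, 0 over the list alone, camera adjusted p = 0.0041), but single wild type libraries spanned -1.23 to 1.05 for this list, and the median was 0.87 without wild type replicate 3 and 0.14 without replicate 1 (camera adjusted p = 0.424; 0.0563 with no filter, and between 4.54e-07 and 0.797 over its alternatives). Slc34a1, the proximal phosphate transporter, chosen after its values were seen, was at 116 FPKM in the knockout library and at 32.8, 79.8 and 142 FPKM in the wild type libraries. With an estimated correlation the adjusted p was 0.607, 0.607 and 0.710 for these 3 lists. Mitochondrially encoded transcripts had a median of 0.23 (0 of 13, camera adjusted p = 0.0534, between 0.0095 and 0.0465 under 5 alternatives and up to 0.803 under the others), which became -0.02 with quantile normalization, 0.10 without wild type replicate 1 and 0.36 without replicate 3. Distal nephron markers had a median of -0.05 (0 of 25, camera adjusted p = 0.969) and podocyte markers one of 0.06 (0 of 12, camera adjusted p = 0.823), which was -0.07 with the same FPKM total. Without wild type replicate 2 these medians turned to 0.11 and -0.01, and the podocyte median was 0.17 without replicate 1 and -0.05 without replicate 3. For the distal nephron list camera's direction was opposite to the median.

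Lists of vessels, injury and proliferation were lower by camera. Endothelial markers had a median of -0.43 (0 of 19 passed, 0 over the list alone, 18 below every wild type library, camera adjusted p = 6.21e-09), with Cdh5 (VE-cadherin) at 15.0 against 28.1 ± 4.46 FPKM. Tubular injury genes had a median of -0.25, inside the range of -0.26 to 0.28 of single wild type libraries (0 of 26, 1 over the list alone, camera adjusted p = 0.0052). Cell cycle genes had a median of -0.22, inside the range of -0.23 to 0.31 of single wild type libraries (0 of 39, 0 over the list alone, camera adjusted p = 0.0020), which became -0.07 without wild type replicate 1 and -0.10 with library weights. Immediate early and heat shock genes had a median of -0.39 (0 of 25, 0 over the list alone, camera adjusted p = 5.32e-07; -0.59 with a pseudocount of 0.1 FPKM), with Dusp1, a stress-induced phosphatase, at 7.02 against 16.2 ± 3.05 FPKM. Urothelium markers, which tell how much of the lining of the renal pelvis a sample holds, had a median of -1.86 with all 10 below every wild type library (0 of 10 passed, 0 over the list alone, camera adjusted p = 7.21e-05; median -2.91 with a pseudocount of 0.1 FPKM). Single wild type libraries spanned -1.84 to 1.15 for that list, and Krt15 was at 0.74 FPKM against 18.9, 26.3 and 4.28 FPKM. With an estimated correlation the adjusted p of these 5 lists lay between 0.607 and 0.710.

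**Figure D3:**
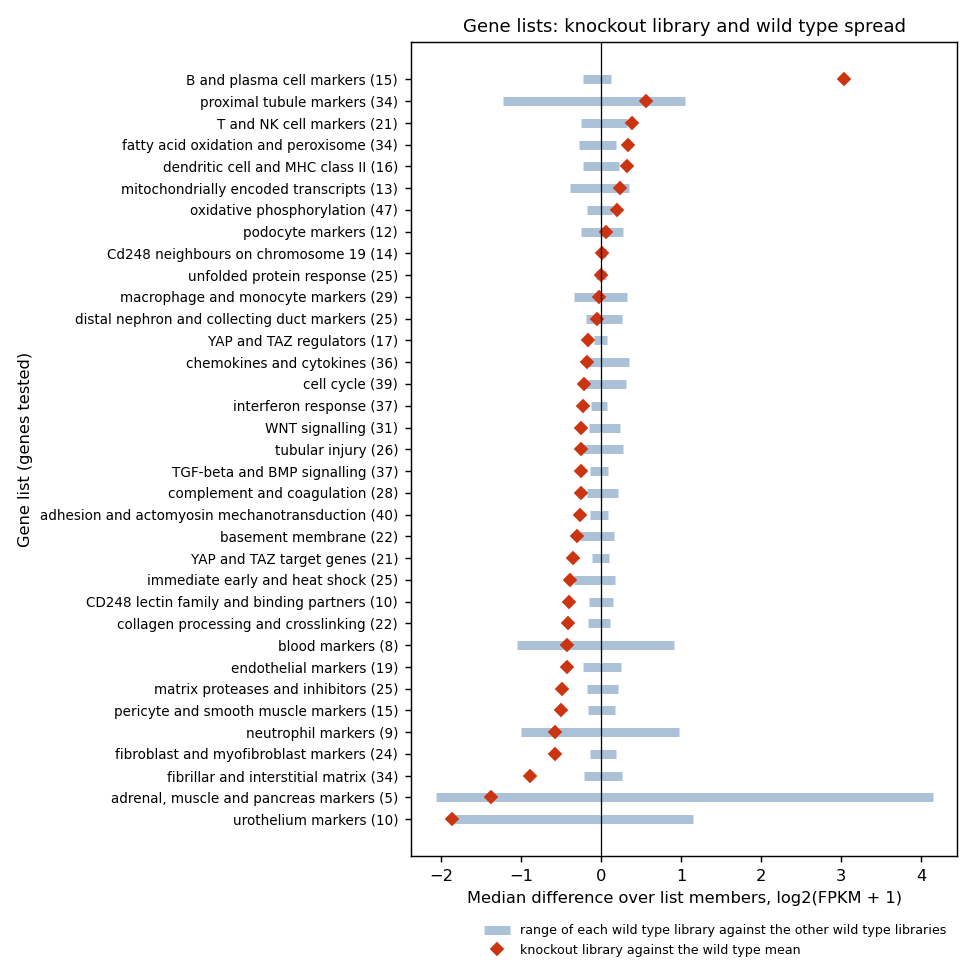
Median difference on the log2(FPKM + 1) scale over the members of each of 35 gene lists, with the number of genes tested in brackets; diamonds are the knockout library against the wild type mean and bars span each wild type library against the other wild type libraries. The diamond of the interstitial matrix list lies at -0.90, outside its bar of -0.22 to 0.26, whereas that of the proximal tubule list lies at 0.55, inside its bar of -1.23 to 1.05.

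Across 3759 annotation terms, camera called 714 at an adjusted p under 0.05, 131 higher and 583 lower in the knockout library, and 0 with an estimated correlation (smallest adjusted p = 0.987). The leading higher terms were made of immunoglobulin genes, which supplied 79 of the 81 tested members of the circulating immunoglobulin complex (median 3.71, camera adjusted p = 3.56e-71). Immunoglobulin genes near 0 in wild type were tested only if high in the knockout library, so the filter partly fixed the direction of this term. Of the 131 higher terms, 116 had no immunoglobulin members, among them the KEGG oxidative phosphorylation pathway (126 genes, median 0.17, camera adjusted p = 9.87e-08) and the KEGG peroxisome pathway (79 genes, median 0.19; 1.80e-06). Lower terms included extracellular matrix (166 genes, median -0.37, camera adjusted p = 3.96e-17), collagen-containing extracellular matrix (229 genes, median -0.31; 2.60e-13) and the KEGG focal adhesion pathway (174 genes, median -0.17; 1.26e-09).

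In the authors' deposited table, 263 genes were marked as significant, 96 higher in the knockout library, of which 52 were immunoglobulin genes, and 167 lower. Of these, 237 were among the genes tested here. The calls shared by both were 44, made up of 30 higher genes and all 14 lower genes.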

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

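The tests without the immunoglobulin genes and with rescaling outside the immunoglobulin and mitochondrial genes were chosen after the data were seen, and the others before. No paired analysis was possible because the knockout and wild type libraries analysed share only replicate number 1. Tests on counts were not run for want of counts, leaving out the knockout library leaves no comparison, the list of adrenal, muscle and pancreas markers had too few tested genes without wild type replicate 2 and with a mean of at least 2 FPKM, and what depth limits could not be measured. Cd248 passed under all 13 alternatives, with adjusted p from 9.73e-04 to 0.0393. The 122 called genes became 39 with a pseudocount of 0.1 FPKM (33 higher, 6 lower), 205 with no filter (201 higher, 4 lower, with 49 of the 122 among them), 1818 at an unadjusted p under 0.05 (868 higher, 950 lower) and 2 without the immunoglobulin genes (1 higher, 1 lower). The fit without the immunoglobulin genes kept the fold changes of the other genes. It changed both the adjustment and the estimate of the spread, with 2.52 prior degrees of freedom against 2.32. How much of the drop in calls came from each was not tested. The cause of the changes with the pseudocount and the filter was not tested. Lower genes numbered 24 with the same FPKM total, which moved the median of all genes by -0.11, and 30 with library weights, and the cause was not tested. Without 1 wild type replicate, calls ranged from 45 to 73, with 41 to 72 higher and 1 to 4 lower, in fits with 1 residual degree of freedom. Of 25 lists called by camera, 6 higher and 19 lower, 0 were called with an estimated correlation (0 higher, 0 lower) and 1 with fry (1 higher, 0 lower). Of 714 terms, 131 higher and 583 lower, 0 were called with an estimated correlation (0 higher, 0 lower), and without 1 wild type replicate the count ranged from 513 to 873, with 79 to 169 higher and 434 to 704 lower. Ighd, which did not pass, had a difference of 0.02 that became -0.0555 with the same FPKM total, -0.0011 with quantile normalization and -0.0798 with library weights, and ranged from -0.17 to 0.146 without 1 wild type replicate. Over the 37 named genes past the threshold besides Cd248, 316 of 462 comparisons kept the call and 146 lost it, and of the 136 others 15 of 1753 gained one. Over the 25 called lists 52 of 350 comparisons lost the call, and over the 10 others 12 of 138 gained one. No named gene or list past the threshold changed direction under any alternative run.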

Other observations

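The tests of the median of all genes, of plasma cell genes outside the immunoglobulin loci, of macrophages and of resident fibroblasts against the whole matrix list, of overlapping Nnt models, of single libraries set apart and of the number of knockout libraries were chosen after the result was seen, and that of the lymphoid tissue median before.

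Transcripts of neighbouring tissues differed between libraries. Wild type replicate 2 held transcripts of the exocrine pancreas, with Prss2 (trypsinogen) at 33.2 FPKM, Pnlip (pancreatic lipase) at 27.1 FPKM and Amy2a5 (pancreatic amylase) at 16.7 FPKM, where the knockout library and wild type replicates 1 and 3 lay between 0 and 0.09 FPKM. Among markers of perirenal fat, Fabp4 (a fatty acid binding protein) was at 10.5 FPKM in the knockout library against 14.5 ± 2.69 FPKM (SD, n = 3), with Adipoq (adiponectin) at 0.33 FPKM in the knockout library and 0.04, 0.77 and 0.13 FPKM in the wild type libraries, and Cfd (adipsin) at 3.66 FPKM against 0, 8.06 and 0 FPKM. The list of adrenal, muscle and pancreas markers had a median difference of -1.38 (0 of 5 passed, camera adjusted p = 0.127, between 0.0411 with library weights and 0.697 over its alternatives). That median ran from -2.65 to -0.13 over the alternatives. Blood markers had a median of -0.43 (0 of 8, camera adjusted p = 0.125, 0.0435 with library weights and up to 0.697 over its alternatives), which became -0.84 without wild type replicate 3 (0.0043) and -0.10 without replicate 2 (0.331), and Ppbp, a platelet chemokine, was at 3.41 FPKM against 26.5, 14.7 and 9.05 FPKM. All 4 libraries carried Y-linked transcripts and almost no Xist: Ddx3y was at 14.5 FPKM in the knockout library and 17.2, 15.8 and 15.6 FPKM in the wild type libraries, and Xist at most at 0.05 FPKM.

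Slpi, a protease inhibitor of secretions, chosen after its values were seen, was at 60.2 FPKM in the knockout library against 3.44 ± 0.73 FPKM (SD, n = 3) in wild type (3.80 on the log2 scale, SE 0.20, past limma's threshold). Its adjusted p was 0.0766 without wild type replicate 1, 0.0249 without replicate 2 and 0.119 without replicate 3. Gm49909, a predicted gene, was at 2.25 FPKM in the knockout library and listed at 0 in the wild type libraries. It was tested only because of its knockout value. Its wild type values had no spread, so its call rests on the spread that limma borrows from other genes. Gm49909 lost that call without any 1 wild type library.

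A scale difference between libraries does not account for the lower matrix and contractile genes in the knockout library, since it would shift every gene alike, while the median difference of all tested genes was -0.0064 and that of the matrix list -0.90 (-0.11 and -1.02 with the same FPKM total). Macrophage markers did not share the fall, and their median lay 0.87 above that of the matrix list (permutation p = 1e-05, the smallest that 100000 resamples can give). That permutation and those below exchanged genes between lists as if independent, so their p-values measure scatter among genes, not between libraries. Macrophages cannot decide whether interstitial tissue was lost evenly, since medians of other immune cells also differed (T and NK 0.38, dendritic and MHC class II 0.32, B and plasma 3.04, neutrophil -0.57). Endothelial (-0.43), pericyte (-0.51), resident fibroblast (-0.52) and urothelium (-1.86) medians were lower too. A difference in the piece sampled may account for part or all of the fall, and for that of the adhesion and signalling lists (-0.17 to -0.36), for which it was not tested. An even loss of all fibroblasts as the whole cause is argued against only weakly. The 9 resident fibroblast genes outside the matrix list had a median of -0.51, which lay 0.38 above that of the whole matrix list (permutation p = 0.0161). Without wild type replicate 2 the gap was 0.35 (permutation p = 0.0780). Of these 9 genes, 7 were also below every wild type library (chance gives 25% per gene), so part of the fall may still come from fewer fibroblasts. The genotype stays an open hypothesis and cannot be told apart from any other property of the 1 knockout library analysed.

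Immunoglobulin and plasma cell genes were higher in the knockout library. Reads shared between immunoglobulin segments do not account for all of it, since 17 plasma cell genes outside those loci had a median difference of 0.40, above 100% of random lists matched on expression, with 5 called. Lymphoid tissue in the piece sampled stays open: its 12 tested genes had a median of 0.39, above 100% of random lists matched on expression (camera's unadjusted p = 0.0085), where a value above 1 had been set beforehand for this source, and one below 0.5 counted against it only if the plasma cell median exceeded 0.5. Of the 12, 8 of which other lists hold too, 8 lay above every wild type library (chance gives 25% per gene), with Cxcl13, a follicle chemokine, at 1.69 against 0.21 ± 0.16 FPKM and, named after their values were seen, Ccl19, a chemokine of T cell zones, at 5.80 against 2.35 ± 1.45 FPKM and Ltb (lymphotoxin beta) at 11.25 against 8.15 FPKM (6.74 to 10.3 FPKM in single libraries), whereas Clu, which injured tubules also express, at 560 against 671 ± 43.9 FPKM and Ccl21a, a lymphatic chemokine, at 8.02 against 14.0 ± 4.72 FPKM lay below. More plasma cells in the knockout kidney may be the source as well, and the genotype cannot be told apart from this 1 library.

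The second Nnt gene model was at 4.42 FPKM in the knockout library and listed at 0 in all wild type libraries, while the first was 3.11 times lower. Of the exonic bases of the second model, 100% are also exonic in the first, so the values may reflect reads divided between overlapping models. That overlap is the same for every library, so it cannot tell why only the knockout library had a value on the second model. The sum of both was 7.74 FPKM against 10.3 ± 0.77 FPKM. A difference in genetic background at this locus was not tested.

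The count of 122 called genes was the highest of the 4 ways to set 1 library apart (1 of 4 as large), and the highest other count was 25, for wild type replicate 2. With 4 splits, no share under 0.05 can be reached. Each wild type library was there set against a group that holds the knockout library, whose difference widens the spread, so counts of 0, 25 and 0 are low by construction and give no value for chance. Against pairs of wild type libraries alone, in fits with 1 residual degree of freedom, 0, 19 and 0 genes passed for the wild type libraries and 53, 73 and 45 for the knockout library. Most of those of the knockout library were immunoglobulin genes, so its counts mainly describe those loci.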
